A study of Mus musculus with 6 samples.

How the data were processed

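Gene expression was measured on 6 Affymetrix whole-transcript arrays of cultured mouse keratinocytes, the epithelial cells of the epidermis, taken from C57BL/6 skin at embryonic day 18.5. The labels' protocols put 2 arrays in each of 3 groups and pool 2 mice on each array. Control arrays came from animals with one conditional Ovol2 allele combined with either 1 lost Ovol1 copy or the K14-Cre transgene, which is active in basal keratinocytes. The Ovol1 KO group had lost both copies of Ovol1, and the Ovol1/2 double knockout (DKO) group had in addition lost Ovol2 in K14-Cre cells. Per the series design text, cells were cultured for 2 to 5 days, given calcium, which triggers keratinocyte differentiation, and kept for another 3 to 5 days. All arrays carry a female sex label.

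The deposited values are intensities on a linear scale, 1 per probe set and array, that the authors had already summarised from the probes. The submitters' processing notes name Affymetrix Expression Console 1.1.1 and PLIER 2.0, with no role for either. The background correction, the normalization between arrays and any filter are not given in the sources used here. The table held 35556 probe sets with 0 missing values, and median intensities per array ran from 174.2 to 203.6. It has no detection call, so a low value was not separated from background. The precision is limited by the number of arrays.

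Each intensity was increased by 16 and log2-transformed, so fold changes are on the log2(intensity + 16) scale and understate the change of dim genes. The quartiles of the 6 arrays differed by up to 0.218 on this scale. This exceeded the limit of 0.2 fixed in advance, and the values were therefore quantile-normalized over all probe sets. Of the probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several and 12146 carried none here. For 21698 of the first kind the Entrez identifier was found in a RefSeq table of assembly GRCm38.p6, and the match changed 0 symbols. Only probe sets with 1 symbol were tested, as 19938 genes. For the 999 genes with more than 1 probe set, the one with the highest mean over the arrays was used. Among the genes called between DKO and control, 28 had a further probe set, and in 2 of these its change had the opposite sign, by no more than 0.5 log2 units.

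Differences were tested with limma 3.58.1 in R 4.3.3. One model with a mean per group was fitted over all 6 arrays, with a variance trend in eBayes, and p-values were adjusted with the Benjamini-Hochberg method over all genes. A gene was called at an adjusted p below 0.05. The labels describe the arrays of a group as biological replicates. For each gene, 1 spread between pools was pooled over the 3 groups, with 3 residual degrees of freedom. It was then drawn towards the trend over all genes, with 3.89 prior degrees of freedom. An adjusted p therefore does not rest on the 2 compared groups alone, and a widely spread group borrows the narrower spread of the others. The group means, SDs and n = 2 refer to arrays. For gene lists, camera from limma was run on 36 lists with a preset correlation of 0.01 between genes and again with the correlation estimated from the data. All gene lists, the rule for named genes and the main tests were fixed before the data were examined. The rule names, per comparison, Ovol1 and Ovol2, then among called genes with no overlap between the groups the 12 largest rises and the 12 largest falls, then up to 4 members of each described list with the smallest p. Predicted genes, unnamed transcripts and the olfactory and vomeronasal receptors were skipped among the largest rises and falls. Where no gene was called, the 6 smallest p-values were named. Genes outside this rule are marked as chosen after their values were seen.

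The procedure was tested on simulated data with the means and spreads of the 19938 genes, 200 of which were changed in the DKO arrays. In the simulated DKO against control comparison, 51.2% of the 2-fold changes and 99.2% of the 4-fold changes were recovered, with 16 false calls per draw on average. The simulated errors were independent between arrays. They held no difference shared by replicate number and no split in sex-linked genes, both seen in the data, so these rates need not carry over. The alternatives were other offsets (1 and 64), the values as deposited, leaving out the dimmest 30% of genes, other eBayes settings, the mean over a gene's probe sets, only the 4 arrays compared, the replicate number as a block, each array left out in turn, and camera on ranks. A fit with the Xist level as a covariate, and one of only the control and Ovol1 KO arrays with the replicate number as a block, were added after the data were seen. Probe sets without a single gene symbol were left out of the main tests.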

Results

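Ovol1 and Ovol2 encode zinc finger transcription factors of epithelial cells. The series asked how gene expression changes during calcium-induced differentiation when keratinocytes lack Ovol1 alone or both genes. It compared 3 groups with 2 arrays each, every array holding RNA of 2 mice. Across genes, arrays correlated with Pearson coefficients from 0.935 to 0.9937, and genes are not independent replicates. The lowest value lay between control 1 and DKO 2 and the highest between control 1 and Ovol1 KO 1. Control 2 and Ovol1 KO 2 correlated at 0.9917, against 0.9786 between the 2 control arrays and 0.978 between the 2 Ovol1 KO arrays. The arrays of these 2 groups thus lay closer by replicate number than by genotype.

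The targeted genes did not separate the groups. Ovol1 had a mean log2 intensity of 10.06 ± 0.30 (SD, n = 2) in the control group, 10.38 ± 0.22 in the Ovol1 KO group and 10.59 ± 0.01 in the DKO group. Its log2 fold change was 0.32 in Ovol1 KO against control (SE 0.21, limma adjusted p = 1) and 0.53 in DKO against control (SE 0.21, adjusted p = 0.30). Ovol2 stood at 8.47 ± 0.49 in control, 8.999 ± 0.008 in Ovol1 KO and 8.51 ± 0.28 in DKO. Its log2 fold change in DKO was 0.04 against control (SE 0.27, adjusted p = 0.98) and -0.48 against Ovol1 KO (SE 0.27, adjusted p = 0.52). Each gene has 1 probe set on this array, and the sources used here do not say whether that probe set lies within the deleted part. The signal of either gene therefore checks no label, and the group names below are those of the labels.

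Sex-linked genes did not follow the female label on all arrays. Xist, the RNA that silences an X chromosome in female cells, lay at log2 intensities of 4.71 and 4.65 in the control arrays, 4.59 in Ovol1 KO 1, 11.97 in Ovol1 KO 2, and 12.12 and 12.26 in the DKO arrays. The Y-linked gene Kdm5d lay at 14.7 in both control arrays and in Ovol1 KO 1, but at 7.50 in Ovol1 KO 2 and at 7.53 and 7.64 in the DKO arrays. The equal values of 14.7 are at the top of the scale, which quantile normalization makes the same on every array. Eif2s3y and Uty, also Y-linked, split the arrays in the same way as Kdm5d. The control and DKO groups thus differed in sex-linked genes as well as in genotype, and the Ovol1 KO group held 1 array of each kind. Several markers of melanocytes, the pigment cells of skin, differed by replicate number, but not all did so strongly. The SD within a group was at most 0.211 for Sox10 and 0.459 for Kit. Tyrp1, which like Dct was chosen after its values were seen, lay at 10.52, 11.05 and 8.46 in replicate 1 of control, Ovol1 KO and DKO, and at 5.81, 5.62 and 5.72 in replicate 2.

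**Figure D1:**
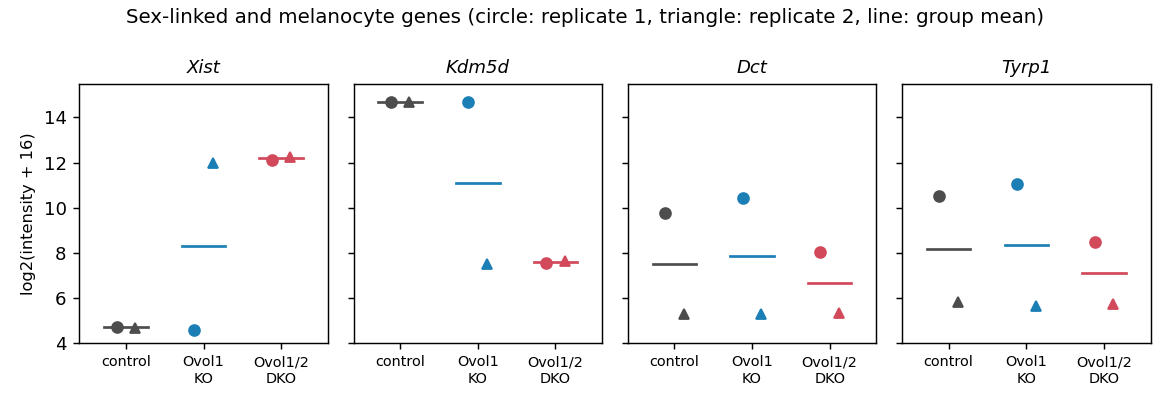
Log2(intensity + 16) on the vertical axis for each of the 6 arrays, by group on the horizontal axis, for the sex-linked genes Xist and Kdm5d and the melanocyte genes Dct and Tyrp1. Circles are replicate 1, triangles replicate 2 and lines group means. Xist was near 12 in Ovol1 KO 2 (11.97) and both DKO arrays (12.12 and 12.26), and Tyrp1 was higher in replicate 1 of every group.

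The first comparison, DKO against control, addressed the loss of both genes together. Among the named genes, Krt1, Krt10 and Zeb1 rose in DKO, while Cldn7 and Epcam fell. Krt1 rose by a log2 fold change of 4.15 (SE 0.64, adjusted p = 0.022) and Krt10 by 4.14 (SE 0.37, adjusted p = 0.0035), which form the keratin pair of differentiating keratinocytes. Zeb1, a repressor of epithelial genes, rose by 3.61 (SE 0.59, adjusted p = 0.027). Cldn7, which encodes a tight junction claudin, fell by 5.41 (SE 0.40, adjusted p = 0.0017), and Epcam, an epithelial adhesion molecule, fell by 3.05 (SE 0.22, adjusted p = 0.0017). Krt1 lay at 14.70 and 12.40 in the DKO arrays. The value of 14.70 is at the top of the scale, which quantile normalization makes the same on every array, and may be capped. With single arrays left out, Krt1 ran from 3.00 to 5.29 in log2 fold change. It lost its call without either Ovol1 KO array, and Zeb1 (2.6 to 4.63) without either Ovol1 KO or either DKO array, while Krt10, Cldn7 and Epcam kept theirs with every array left out. Of the 80 called changes that the naming rule gives in this comparison, 38 did so. In total, limma called 188 genes higher and 451 lower in DKO among 19938 tested, and 164 of the rises and 383 of the falls were at least 2-fold. Without DKO 1 the counts were 67 higher and 191 lower, without DKO 2 they were 120 and 189, and without control 1 they were 177 and 285. Xist was higher in the DKO arrays by 7.51 (SE 1.99, adjusted p = 0.12). In a fit with Xist as a covariate, 3 genes were higher and 5 lower. All 639 log2 fold changes kept their sign in that fit, at a median of 0.872 times their value without the covariate, while their SE grew by a median factor of 1.76. The spread behind these calls includes that between the 2 Ovol1 KO arrays, so genes that separate those arrays were less likely to be called. Over the 464 genes called from the control and DKO arrays alone, which include Xist and Kdm5d, the median was 0.842 and 458 kept their sign. Xist barely varied within the control group or within the DKO group. The covariate therefore rests almost wholly on Ovol1 KO 1 and Ovol1 KO 2, with Xist at 4.59 and 11.97. Those arrays also differ in replicate number, so the fit does not isolate sex.

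Further genes were named as the largest rises in DKO. Aadacl2fm1, an arylacetamide deacetylase-like gene, rose most among the called genes named, by 5.99 (SE 0.27, adjusted p = 0.00028), and its relative Aadacl2 rose by 4.23. The control mean of Aadacl2 was 5.72, near the low end of the scale, and its rise was 4.70 with an offset of 1 and 3.37 with an offset of 64. Mmp27, a matrix metalloproteinase, rose by 4.87, and Postn, which encodes the matrix protein periostin, by 4.16. The transcription factor gene Pou2f3 rose by 4.72, Gsdmc by 4.64, Akr1d1 by 4.48 and Clca3a2 by 4.10. The protease inhibitor genes Stfa3 and Stfa2 rose by 4.84 and 4.49. Akr1d1 lost its call without either DKO array, and Postn without DKO 1. Stefin, Clca and glutathione transferase (Gstm) genes have close paralogues, so their probe sets may not separate the copies.

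Further genes were named as the largest falls in DKO. Mal, which encodes a lipid raft protein of apical transport, fell by 5.98 (SE 0.39, adjusted p = 0.0012), and the ATP-gated channel gene P2rx2 fell by 5.85 (SE 0.26, adjusted p = 0.00028). Dynap fell by 5.63, the phosphatase gene Dusp4 fell by 5.36, and the thrombin receptor family gene F2rl2 fell by 5.34. Ppbp, a chemokine gene, fell by 4.82, and Arg1, which encodes arginase, fell by 4.80. The log2 fold change was -4.78 for Clca3b, -4.72 for Cldn6, -4.66 for the serine protease gene Tmprss11e and -4.60 for the tetraspanin gene Tspan1. In DKO several of these genes lay near the low end of the scale, with mean log2 intensities of 4.52 for Cldn7, 4.84 for Tspan1, 5.04 for Ppbp, 5.26 for Cldn6, 5.32 for Dusp4 and 5.40 for P2rx2. No detection call tells whether such levels were above background. The sizes and the order of these falls therefore depend on the offset of 16. With an offset of 1 the log2 fold change was -6.93 for Cldn7 and -6.49 for P2rx2, and with an offset of 64 it was -3.85 and -4.78. Dusp4 lost its call without either DKO array, Cldn6 without DKO 2 and Arg1 without either Ovol1 KO array, and the values of Arg1 ran from -6.26 to -3.34 with single arrays left out.

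**Figure D2:**
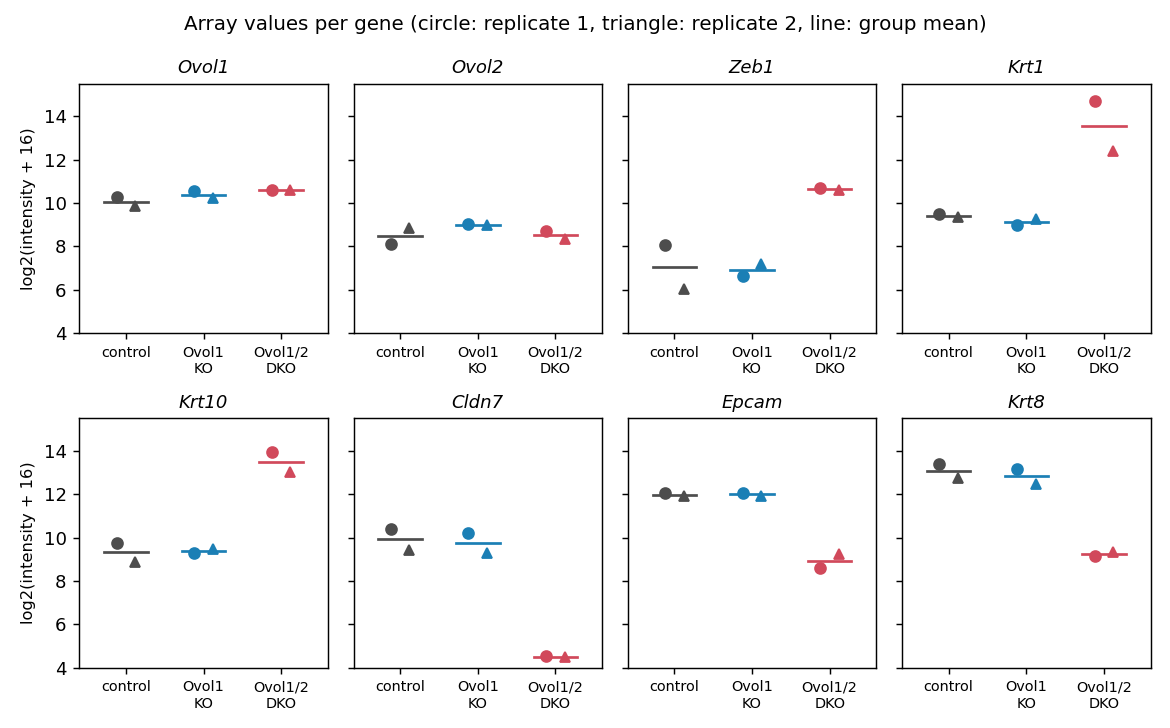
Log2(intensity + 16) on the vertical axis for each of the 6 arrays, by group on the horizontal axis, for 8 genes. Circles are replicate 1, triangles replicate 2 and lines group means. Zeb1, Krt1 and Krt10 were higher and Cldn7, Epcam and Krt8 lower in both DKO arrays than in the other 4 arrays, whereas Ovol1 and Ovol2 were not lower in DKO than in control (log2 fold changes 0.53 and 0.04).

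Among the lists fixed in advance, epithelial identity genes had the smallest camera p. Of 22 measured members 11 fell, 0 rose and 11 did not pass, and 17 fell when adjusted over the list alone. Besides Cldn7 and Epcam, the tight junction gene Marveld3 fell by 2.80 and the membrane protease gene Prss8 fell by 2.27. The camera adjusted p was 1.9e-14 with the preset correlation, against an adjusted p = 0.52 with an estimated correlation. Of 24 adherens and tight junction genes 7 fell, 0 rose and 17 did not pass, and 1 rose and 14 fell when adjusted over the list alone. The rise was that of Nectin1, chosen after its values were seen, with a log2 fold change of 0.76. Cldn3 fell by 4.06 and Cldn4 fell by 1.59 (camera adjusted p = 1.8e-10, and adjusted p = 0.52 with an estimated correlation). Of 8 simple epithelium keratins 4 fell and 4 did not pass, and the same counts held when adjusted over the list alone. The log2 fold change was -3.81 for Krt8, -3.32 for Krt7, -4.03 for Krt18 and -4.15 for Krt19 (camera adjusted p = 0.00083, and adjusted p = 0.52 with an estimated correlation). This call was also lost with camera on ranks (adjusted p = 0.065), and Krt19 lost its own call with an offset of 1 (log2 fold change -4.45). The DKO arrays stood apart for Krt18 (10 and 7.43) and Krt19 (8.53 and 5.58). With single arrays left out the values ran from -5.31 to -2.74 for Krt18 and from -5.62 to -2.68 for Krt19. Both lost their call without either Ovol1 KO array, and Krt18 also without control 1 or DKO 2. Cldn7, Marveld3 and Cdh1 belong to both of the first lists. Of 14 desmosome genes 0 passed in limma and 1 had an unadjusted p below 0.05. Their median was -0.02 and became 0.02 with the values as deposited (camera adjusted p = 0.68). Xist was 7.51 higher in the same DKO arrays.

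Differentiation lists moved in both directions. Of 14 spinous genes 3 rose and 11 did not pass, and 7 rose when adjusted over the list alone. They were Krt1, Krt10 and Skint3, which rose by 3.74 from a control mean of 5.42 (camera adjusted p = 8.9e-06, and adjusted p = 0.52 with an estimated correlation). As that mean is near the low end of the scale, the rise depends on the offset and was 4.33 with an offset of 1 and 2.77 with an offset of 64. Of 46 cornified envelope genes 2 rose, 0 fell and 44 did not pass, with a median of -0.31 (camera adjusted p = 0.063, and adjusted p = 0.026 on ranks). The 2 were Lor, which encodes loricrin and rose by 1.95, and the transglutaminase gene Tgm3, which rose by 2.68. With single arrays left out the rise ran from 1.55 to 2.35 for Lor and from 1.8 to 3.56 for Tgm3. Lor lost its call without DKO 2, and Tgm3 without either Ovol1 KO array. When adjusted over the list alone, 2 rose and 1 fell. Of 23 epidermal barrier lipid genes 1 rose, the fatty acid elongase gene Elovl4 by 0.73, and 22 did not pass, with 3 rises when adjusted over the list alone (camera adjusted p = 0.044, adjusted p = 0.52 with an estimated correlation and adjusted p = 0.065 on ranks). Of 20 stratum corneum proteases and inhibitors 4 fell and 16 did not pass. Besides Prss8, the log2 fold change was -4.42 for Tmprss11d, whose DKO mean was 5.26, -1.81 for St14 and -1.29 for Klk8 (camera adjusted p = 0.013, adjusted p = 0.72 with an estimated correlation and adjusted p = 0.1 on ranks). When adjusted over the list alone, 1 rose and 5 fell. Of 24 differentiation transcription regulators 4 rose and 2 fell (camera adjusted p = 0.088), with 6 rises and 3 falls when adjusted over the list alone. Maf rose by 2.32 and Gata3 by 1.16, while Elf3 fell by 1.67 and Prdm1 fell by 2.30. Of 17 basal keratinocyte genes 1 rose and 1 fell, with 2 rises and 5 falls when adjusted over the list alone (camera adjusted p = 0.20). Their median was -0.20 and their mean 0.03. Krt15 rose by 4.06, while the integrin gene Itgb4 fell by 0.79. Xist again separated the same arrays by 7.51.

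Of 15 transcription regulators of the epithelial-mesenchymal transition, Zeb1 rose, Foxc2 fell by 2.64, to a mean of 5.43, and Foxc1 fell by 2.04, and 12 did not pass (camera adjusted p = 0.34). When adjusted over the list alone, 1 rose and 3 fell. Of 23 mesenchymal genes 3 rose, 2 fell and 18 did not pass (camera adjusted p = 0.27), with 4 rises and 6 falls when adjusted over the list alone. The collagen receptor gene Ddr2 rose by 2.11, Tgfbi by 2.42 and the gelatinase gene Mmp2 by 1.62, while the fibronectin gene Fn1 fell by 1.92. Of 26 actin cytoskeleton and motility genes 4 fell and 22 did not pass, with 1 rise and 7 falls when adjusted over the list alone. The log2 fold change was -1.07 for Fscn1, -0.78 for Actn1, -0.62 for Cttn and -0.41 for Actn4 (camera adjusted p = 9.7e-08, and adjusted p = 0.52 with an estimated correlation). Of 30 wound and stress keratinocyte genes 3 rose and 3 fell. Il33 rose by 3.38 together with Stfa2 and Stfa3, while the chemokine gene Cxcl5 fell by 3.17, to a DKO mean of 5.63, its relative Cxcl1 fell by 3.40 and the cytokine gene Il1a fell by 3.87. Cxcl1 and Il1a were chosen after their values were seen. The list had 3 rises and 11 falls when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.72 with an estimated correlation). Of 20 unfolded protein response genes 0 passed in limma, also when adjusted over the list alone, and 4 had an unadjusted p below 0.05, with a median of -0.31 (camera adjusted p = 0.0025, and adjusted p = 0.72 with an estimated correlation). The arrays compared here also differed by 7.51 in Xist.

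Signalling and matrix lists that were not called by camera still held called genes. Of 20 TGF-beta genes 1 fell, the ligand gene Tgfb2 by a log2 fold change of -2.41 (camera adjusted p = 0.18), with 3 falls when adjusted over the list alone. Of 25 Wnt genes the ligand gene Wnt3 rose by 2.81 and Dkk3 fell by 1.11 (camera adjusted p = 0.34), with 2 rises and 2 falls when adjusted over the list alone. Of 27 basement membrane and matrix protease genes 1 rose, Mmp3 by 2.69, and 5 fell (camera adjusted p = 0.088), with 4 rises and 7 falls when adjusted over the list alone. The urokinase receptor gene Plaur fell by 3.87, Lama4 fell by 2.13 and Timp2 fell by 1.79. Of 22 NRF2 responsive genes 3 rose and 1 fell (camera adjusted p = 0.48), with 4 rises and 6 falls when adjusted over the list alone. The glutathione transferase genes Gstm1 and Gstm3 rose by 2.10 and 1.83, and the heme oxygenase gene Hmox1 fell by 2.13. Of 24 interferon responsive genes 2 fell, with log2 fold changes of -1.58 for Ifit2 and -1.95 for Rsad2 (DKO means 5.69 and 5.80), also when adjusted over the list alone (camera adjusted p = 0.27). Of 39 cell cycle genes 0 passed in limma and 1 had an unadjusted p below 0.05, with a median of 0.22 (camera adjusted p = 0.058, and adjusted p = 0.013 on ranks). Xist differed by 7.51 between the same arrays.

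**Figure D3:**
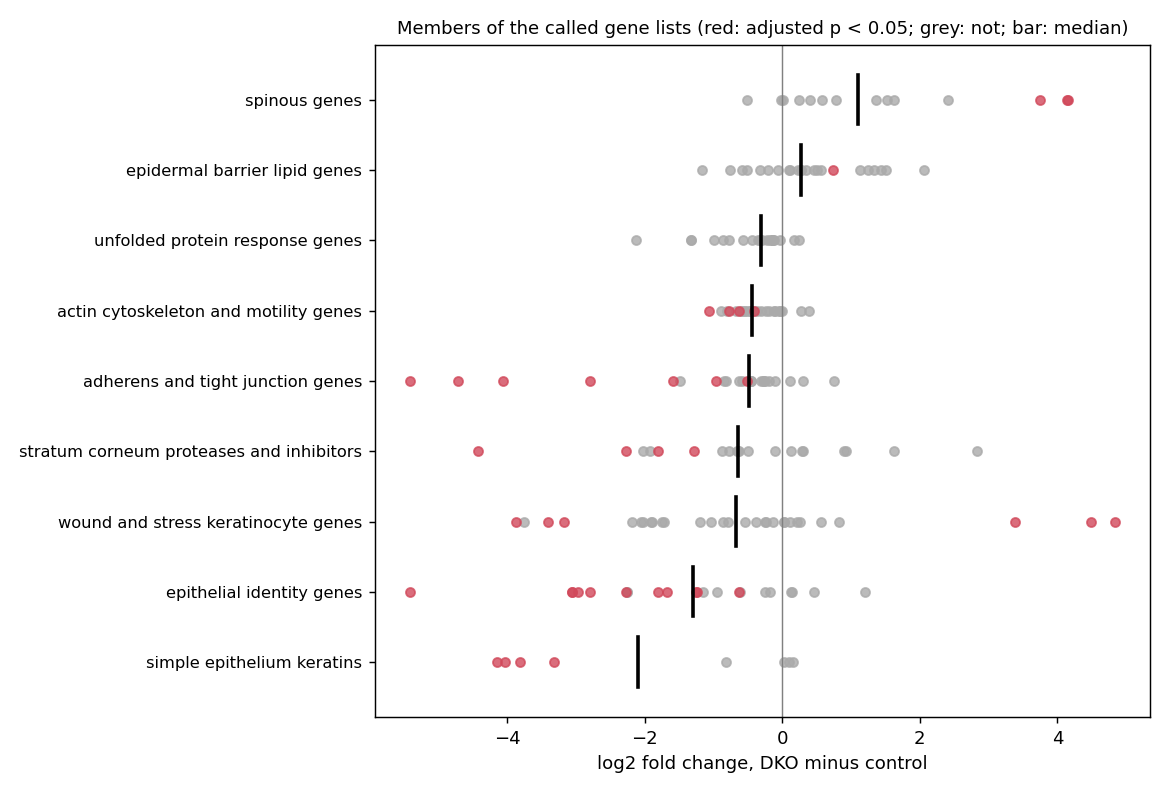
Log2 fold change of DKO minus control on the horizontal axis for each measured member of the 9 gene lists called by camera with a preset correlation. Red points are genes with an adjusted p below 0.05, grey points are the others, and black bars are list medians. Epithelial identity genes had 11 falls among 22 members, and spinous genes 3 rises among 14.

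Markers of other cell types mostly did not pass. Of 19 fibroblast markers Postn rose, Pdgfra fell by 1.06 and 17 did not pass, with a median of 0.12 and a mean of 0.51 (camera adjusted p = 0.20). When adjusted over the list alone, 3 rose and 1 fell. The log2 fold changes of Dpp4 and Col5a2, which did not pass over all genes, were 2.72 (adjusted p = 0.057) and 0.81 (adjusted p = 0.072). The abundant fibroblast collagen gene Col1a1 lay at log2 intensities of 8.47 and 8.91 in the DKO arrays and 8.43 and 8.55 in the control arrays. In the same order, Col1a2 lay at 8 and 8.57 against 8.16 and 8.18, Col3a1 at 8.14 and 8.69 against 8.22 and 8.25, and Dcn at 7.88 and 8.73 against 7.22 and 7.72. DKO 2 was thus above both control arrays for these 4 genes, and DKO 1 for Dcn alone. Of 12 melanocyte markers 1 passed, the receptor gene Kit, which fell by 1.43 (camera adjusted p = 0.081, and adjusted p = 0.033 on ranks). The fat cell list held 1 fall among 9 members, Cidea, which fell by 2.88, and the Schwann cell list 1 among 8, Mbp, which fell by 1.15. Adjusted over the list alone, each of these 3 lists also had 0 rises and 1 fall. Of 24 immune, 12 endothelial, 19 muscle and 5 red blood cell markers 0 were called by limma, and 4 of these 60 genes had an unadjusted p below 0.05. The basal keratin gene Krt14 lay at 13.64 and 13.61 in DKO and at 13.63 and 13.61 in control. Col1a1, Col1a2, Col3a1, Dcn and Krt14 were chosen after their values were seen.

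The second comparison, Ovol1 KO against control, addressed the loss of Ovol1 alone. No gene was called by limma, with 0 higher and 0 lower, and the smallest adjusted p was 1. At an unadjusted p below 0.05 there were 162 genes, which is 0.813% of those tested. Unchanged genes alone would give a share of about 0.05 in a calibrated test. This fit was therefore conservative, and the absence of calls is weak evidence that nothing changed. The 6 genes with the smallest p did not pass the threshold. Their log2 fold changes were 0.98 for Clca4b, 1.02 for Them5, -0.97 for Dnase1l2, -1.14 for Rnase2b, 0.60 for Slc39a8 and 1.01 for Ret, each with an adjusted p of 1. Among all genes, 36 moved by over 2-fold in the group mean, called or not, against 1154 in DKO against control. With the replicate number as a block over all 6 arrays, limma also called 0 genes. In a fit of only the control and Ovol1 KO arrays with that block, chosen after the data were seen, limma called 48 genes higher and 85 lower. The labels do not pair these arrays, and each gene then had 1 residual degree of freedom against 19.8 from the prior. A disagreement between the array pairs of a gene therefore counted little. Without Ovol1 KO 1, limma called 4 genes, Xist higher and Kdm5d, Eif2s3y and Uty lower.

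Camera with the preset correlation called 7 of 36 lists in Ovol1 KO against control, although 0 of their 171 members passed in limma and 4 had an unadjusted p below 0.05. For all 7 lists the call was lost, with adjusted p = 0.98 with an estimated correlation. Camera on ranks called 5 lists, which left out 3 of the 7, the Ovol genes (adjusted p = 0.37), the interferon responsive genes and the regulators of the epithelial-mesenchymal transition (both adjusted p = 0.059), and added epithelial identity genes (adjusted p = 0.045). Cell cycle genes had a median of 0.14 over 39 members (camera adjusted p = 1.8e-07), with log2 fold changes of 0.39 for Mcm6 and 0.19 for Pcna, which act in DNA replication. Cornified envelope genes had a median of -0.32 over 46 members (camera adjusted p = 0.0064), with -1.04 for Sprr2e and -1.26 for Sprr2i, which are close paralogues. Interferon responsive genes had a median of 0.05, with 0.44 for Ifit3 (camera adjusted p = 0.0094), and unfolded protein response genes a median of -0.19, with -0.70 for Ddit3 (camera adjusted p = 0.033). Differentiation regulators had a median of 0.09 (camera adjusted p = 0.0064), and regulators of the epithelial-mesenchymal transition a median of 0.14 (camera adjusted p = 0.027). The list of the 3 Ovol genes had a median of 0.32 (camera adjusted p = 0.0497). None of these lists had a member that passed when adjusted over the list alone. The Ovol1 KO group held 1 array with the Xist level of the control group and 1 with that of the DKO group. With the values as deposited, 4 lists were called, and leaving out 1 array of either group gave 11 to 13. The 4 counts were 12 without control 1, 11 without control 2, 13 without Ovol1 KO 1 and 11 without Ovol1 KO 2.

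The third comparison, DKO against Ovol1 KO, addressed what the additional loss of Ovol2 added. Krt1 rose by 4.43 (SE 0.64, adjusted p = 0.022), Krt10 by 4.09 (SE 0.37, adjusted p = 0.0039) and Zeb1 by 3.72 (SE 0.59, adjusted p = 0.030). Cldn7 fell by 5.23 (SE 0.40, adjusted p = 0.0021), Epcam fell by 3.06 (SE 0.22, adjusted p = 0.0019) and Krt19 fell by 4.99 (SE 0.82, adjusted p = 0.034). Further large rises were those of Aadacl2fm1 by 6.31, Mmp27 by 4.66, Gsdmc by 4.61, Pou2f3 by 4.60, Postn by 4.37 and Stfa2 by 4.20. Akr1d1 rose by 4.06, the atypical chemokine receptor gene Ackr4 by 4.05, Igfbp4 by 3.74 and Aadacl2 by 3.72. Among the falls, the log2 fold change was -5.85 for Mal, -5.67 for Dynap, -5.14 for Clca3b, -5.07 for P2rx2, -5.00 for Dusp4 and -4.97 for F2rl2. It was -4.81 for Arg1, -4.72 for Tspan1, -4.61 for Tmprss11d and -4.59 for Psca. The DKO means near the low end of the scale enter here too, and with an offset of 64 Dusp4 lost its call (log2 fold change -3.92). Akr1d1 lost its call with an offset of 1 (log2 fold change 4.22). Of the 65 called changes that the naming rule gives here, 23 kept their call with every array left out, among them those of Cldn7 and Epcam. Krt1, Zeb1 and Krt19 lost theirs without either Ovol1 KO array, Zeb1 also without either DKO array, and Krt10 without Ovol1 KO 1. Akr1d1, Postn, Dusp4, Arg1, Tmprss11d and Psca also lost theirs with at least 1 array left out. Values ran from 3.28 to 5.58 for Krt1, from -6.47 to -3.52 for Krt19, from -6.27 to -3.35 for Arg1 and from -5.95 to -3.24 for Psca. They ran from 3.14 to 4.97 for Akr1d1 and from -6.1 to -3.9 for Dusp4.

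In total, limma called 131 genes higher and 298 lower in DKO than in Ovol1 KO. Of these, 117 and 286 were also called in the same direction against control, where 1.24 and 6.74 would be shared by independent lists. Both comparisons use the same DKO arrays, which by itself raises the overlap. In the fit with Xist as a covariate, 18 genes were higher and 55 lower. All 429 log2 fold changes kept their sign there, at a median of 0.941 times their value without the covariate, while their SE grew by a median factor of 1.26. These genes were called with the same spread between the Ovol1 KO arrays, and the covariate again rests almost wholly on those arrays. The counts moved with every array left out. They were 235 higher and 503 lower without control 1, 228 and 506 without control 2, 23 and 65 without Ovol1 KO 1, 67 and 150 without Ovol1 KO 2, 48 and 147 without DKO 1, and 91 and 141 without DKO 2. Without Ovol1 KO 1, the remaining array Ovol1 KO 2 had the same Xist level as the DKO arrays, and 86 of the 88 genes called there were also called with all arrays.

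Camera called 13 of 36 lists in DKO against Ovol1 KO. Of 22 epithelial identity genes 11 fell (camera adjusted p = 1.2e-19, and adjusted p = 0.38 with an estimated correlation), among them Marveld3, which fell by 2.96, and Elf3, which fell by 1.86. When adjusted over the list alone, 17 fell. Of 24 adherens and tight junction genes 5 fell, with 1 rise and 14 falls when adjusted over the list alone (camera adjusted p = 1.3e-14, and adjusted p = 0.38 with an estimated correlation). Cldn3 fell by 4.11 and Cldn4 fell by 1.53. Of 14 spinous genes 3 rose and 11 did not pass, with 7 rises when adjusted over the list alone (camera adjusted p = 5.3e-05, and adjusted p = 0.55 with an estimated correlation). Of 8 simple epithelium keratins 3 fell, among them Krt8 (log2 fold change -3.57) and Krt7 (-2.95), with 4 falls when adjusted over the list alone (camera adjusted p = 0.00021, and adjusted p = 0.54 with an estimated correlation). Of 24 interferon responsive genes 2 fell, Rsad2 (log2 fold change -2.06) and Ifit2 (-1.34), with 3 falls when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.76 with an estimated correlation). Of 12 melanocyte markers Kit fell by 2.14, which was also the only fall when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.76 with an estimated correlation). The remaining calls were those of actin cytoskeleton genes (camera adjusted p = 1e-08), stratum corneum proteases (0.00059), wound and stress genes (0.0047), barrier lipid genes (0.021), regulators of the epithelial-mesenchymal transition (0.032), unfolded protein response genes (0.046) and TGF-beta genes (0.049). With an estimated correlation the adjusted p of these 7 lists ran from 0.54 to 0.84. Of the 13 lists, 4 were not called in DKO against control, with a camera adjusted p there of 0.27 for interferon responsive genes, 0.081 for melanocyte markers, 0.34 for regulators of the epithelial-mesenchymal transition and 0.18 for TGF-beta genes. The difference between the comparisons was not tested. With an estimated correlation camera called 0 lists. On ranks it called 10, without simple epithelium keratins (adjusted p = 0.057), regulators of the epithelial-mesenchymal transition (0.23) and TGF-beta genes (0.15). Of 19 fibroblast markers Postn and Col5a2 rose, the latter by 1.04, and 17 did not pass, with 5 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.43). Their median was 0.17 and their mean 0.56.

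The changes of Ovol1 KO and of DKO against the same 2 control arrays were also compared across the 19938 genes. The Pearson correlation of the log2 fold changes was 0.334, where 100 simulated pairs of unchanged groups against shared controls gave 0.501 on average, from 0.475 to 0.527. The covariance was 0.0339, against a simulated mean of 0.0294 and a highest simulated value of 0.0324. The simulated arrays were independent, and both simulated mutant groups were unchanged. In the data, the differences between replicates 1 and 2 correlated at 0.687 between control and Ovol1 KO, and DKO held called changes. Neither the correlation nor the covariance can therefore be tested against these simulated values. Without Ovol1 KO 2 the correlation was -0.0761, and without control 2 it was 0.601. No gene was called by limma in both comparisons, as 0 were called in Ovol1 KO, where 162 had an unadjusted p below 0.05. With 2 control arrays the controls could not be split, so the part that sharing them adds was taken from the simulation alone.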

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

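Of the tests here, the one on genes next to Ovol1 and Ovol2 was set before its result was seen, and the other tests were chosen after the pattern had been seen. Probe sets without a single gene symbol were outside the comparisons of genes. When all 35556 probe sets were fitted together, limma called 306 between DKO and control, against 639 genes in the main fit. Of the 306, 28 were among the 13767 probe sets with no symbol or several, 9 higher and 19 lower. Between DKO and Ovol1 KO 181 probe sets were called, against 429 genes in the main fit. Of the 181, 11 were among the 13767, 3 higher and 8 lower. Tested on their own, 0 of the 13767 were called by limma in either comparison, and 818 and 792 had an unadjusted p below 0.05.

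The largest pattern was the 639 genes called between DKO and control. If a difference in sex were the whole cause, the Ovol1 KO group, with 1 array of each kind, would lie midway, and the change of DKO against Ovol1 KO would be about 0.5 of that against control, as it was for Xist (0.521). Over the 464 genes called from the control and DKO arrays alone, a choice in which the Ovol1 KO arrays take no part, the median ratio was 0.907 (quartiles 0.821 and 0.977), which argues against sex as the whole cause, while a part of sex in single genes stays open. DNA of another strain kept around the targeted genes would place the calls there, but 1.1% of the called genes lay among the 100 nearest genes on each side of Ovol1 or Ovol2, against 1.93% of all genes. Fibroblasts in place of keratinocytes would raise the fibroblast list by several log2 units, but its median was 0.12 with quartiles of -0.19 and 0.82, so that a smaller share of fibroblasts and the genotype itself, which may account for the rest as a hypothesis, stay open.

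The second pattern was the split of the arrays in sex-linked genes against their female label. Pools of both sexes would show high Xist and high Kdm5d on 1 array, and 0 of 6 arrays did. Whether the array labelled Ovol1 KO 1 could hold control RNA cannot be told apart from a correct label, because Ovol1 signal did not separate the groups. The Ovol1 log2 intensity of Ovol1 KO 1 was 0.307 above that of Ovol1 KO 2, and neither array lay below both control arrays. Animals of different sex in different pools remain an open explanation, and no other was tested.

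The third pattern was the absence of calls between Ovol1 KO and control over all arrays. Many large changes hidden by the small number of arrays would have moved many group means, but over 2-fold 36 genes moved against 1154 in DKO, which argues against them. Differences shared by arrays of 1 replicate number may have hidden smaller changes, since limma called 133 genes from the control and Ovol1 KO arrays alone with that number as a block, at a median absolute log2 fold change of 0.741. The 133 calls assume that the numbers pair the arrays, and they include Xist, which moved in Ovol1 KO 2 alone. Of these genes, 80 moved the same way in both pairs with the smaller change at least 0.5 times the larger, and 53 did not. Selection by the fit favours genes that moved the same way in both pairs, so this tally is no test of the calls. The choice of controls, some of which had lost 1 copy of Ovol1 per the labels, stays open, and no biological explanation was tested.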

How the results depend on the processing

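The fit with Xist as a covariate and the blocked fit of 4 arrays were chosen after the data were seen. Offsets, values as deposited, the filter on dim genes, the eBayes settings, the mean over probe sets and, against control, the fit of only the 4 arrays compared kept the counts of called genes within 1.5 times. Between DKO and Ovol1 KO, the fit of only the 4 arrays called 239 higher and 499 lower. A fit of all 35556 probe sets called fewer, 306 probe sets in DKO against control and 181 in DKO against Ovol1 KO. With Xist as a covariate, limma called 3 higher and 5 lower in DKO against control and 18 and 55 in DKO against Ovol1 KO. The loss comes with larger errors, as the median SE of the 639 genes rose from 0.228 to 0.377 while their median absolute log2 fold change went from 1.66 to 1.44. Lists called then numbered 17 in DKO against control and 11 in Ovol1 KO against control. With an estimated correlation camera called 0 lists in each comparison. The smallest camera adjusted p-values were 0.52 in DKO against control, 0.98 in Ovol1 KO against control and 0.38 in DKO against Ovol1 KO. For barrier lipid genes the estimated correlation was -0.0032, below the preset 0.01. Their camera adjusted p in DKO against control still rose from 0.044 to 0.52. A call lost in this variant is therefore not evidence of correlation among the members of a list. With the preset correlation and dim genes left out, camera called 7 lists in DKO against Ovol1 KO. With the values as deposited it called 4 in Ovol1 KO against control. The cause was not tested for these list counts.

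The groups share only replicate numbers, which were not taken as pairs. With the replicate number as a block, 301 genes were higher and 768 lower in DKO against control, 225 and 580 in DKO against Ovol1 KO, and 0 in Ovol1 KO against control, where limma gave 363 at an unadjusted p below 0.05. The blocked fit of only the control and Ovol1 KO arrays called 48 higher and 85 lower, with 1374 at an unadjusted p below 0.05, while without the block these 4 arrays gave 0 calls and 201. The differences between replicates 1 and 2 correlated across genes at 0.687 between control and Ovol1 KO, 0.151 between control and DKO and 0.0875 between Ovol1 KO and DKO.

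Leaving out 1 array leaves a group with 1 array, which is assumed to vary like the other groups. Called genes then ranged from 67 to 188 higher and 189 to 547 lower in DKO against control, with 8 to 15 lists. In Ovol1 KO against control the ranges were 0 to 1 higher, 0 to 3 lower and 6 to 13 lists, and in DKO against Ovol1 KO 23 to 235 higher, 65 to 506 lower and 9 to 17 lists. Genes called in both Ovol1 KO and DKO ranged from 0 to 4. The 4, which are Xist and 3 Y-linked genes, appeared without Ovol1 KO 1. The correlation of the 2 sets of changes ranged from -0.0761, without Ovol1 KO 2, to 0.601, without control 2. The cause was not tested. Over 151 log2 fold changes of named genes, 2410 values under the alternatives were computed. Of these, 1991 kept direction and side of the threshold, 419 kept the direction but lost the call and 0 changed sign with a call on either side. The compared groups did not overlap in any of the 639 and 429 called genes. Leaving out 1 array could therefore not reverse the sign of a called gene, and the lack of reversals there is no test. Intensities near the low end of the scale limit the size of falls such as those of Cldn7 and P2rx2.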

Other observations

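The genes of this paragraph were chosen after their values were seen, and no enrichment was tested for them. In DKO against control, genes of apical polarity and sodium transport were among the falls called by limma. Crb3, which encodes an apical polarity protein, fell by 3.13, and the log2 fold change of its partners was -1.86 for Pard6b and -1.77 for Prkcz. For the epithelial sodium channel subunit genes it was -2.52 for Scnn1a and -2.41 for Scnn1g. Genes of retinoid handling moved in both directions. Rdh10, which makes retinal, fell by 3.29, Aldh1a3, which makes retinoic acid, fell by 3.65 and Crabp1 fell by 2.20, while Rbp2 rose by 2.65. The log2 fold change was -2.89 for Sema3c, -2.18 for Sema3e, -2.87 for Sema4f and -3.18 for Sema7a, all semaphorin genes, and -2.47 and -3.89 for the neuropilin genes Nrp1 and Nrp2. Cytokine receptor genes were among the rises, with 3.72 for Il22ra2, 2.08 for Il20rb, 1.58 for Il13ra1, 1.33 for Il6ra and 1.13 for Il6st. Each value is from 2 arrays per group, and Xist differed by 7.51 between the same arrays.

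Genes outside the naming rule in this and the following paragraphs were chosen after their values were seen. In the gene order of assembly GRCm38.p6, 1 run of at least 3 neighbouring tested genes rose together in DKO against control, where shuffled calls gave 0.01 runs on average. It held 4 genes on chromosome 3, Aadacl2fm1 (5.99), Gm9696 (4.73), Aadacl2 (4.23) and Aadac (2.14), all of the arylacetamide deacetylase family or unnamed. These are relatives in sequence, and cross-hybridisation between them was not tested. Of falling genes there was also 1 run, with 3 genes (Prss22, Prss27 and Kctd5), against 0.21 in shuffled calls.

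The position of each array between control and DKO was computed over the 639 called genes. Genes that separate the Ovol1 KO arrays were less likely to be among them. The distance from DKO, as a multiple of the DKO minus control change, had a median of 0.979 for Ovol1 KO 1 and 0.842 for Ovol1 KO 2. For control 1 and control 2 it was 1.02 and 0.978. Over the 464 genes called from the control and DKO arrays alone the median for Ovol1 KO 2 was 0.831, and over the 35 of them outside the 639 it was 0.5. Those 35 were not called once the spread between the Ovol1 KO arrays entered, so a gap between these arrays is partly built into their choice. For 13 genes Ovol1 KO 2 lay nearer to DKO than to control, and for 6 genes Ovol1 KO 1 did. Krt15 stood at 8.999 in Ovol1 KO 1 and 10.98 in Ovol1 KO 2, against 8.04 and 9.05 in control and 13.04 and 12.16 in DKO. Stfa3 stood at 8.70 and 10.16 in the Ovol1 KO arrays, against 8.33 and 7.76 in control and 12.89 and 12.88 in DKO.

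In the blocked fit of only the control and Ovol1 KO arrays, chosen after the data were seen, 14 of 46 cornified envelope genes were called lower and 0 higher in Ovol1 KO, and 24 lower and 0 higher when adjusted over the list alone. Kprp differed by -1.03 between the arrays numbered 1 and by -1.41 between those numbered 2, and Lce1a1 by -1.12 and -1.28. Genes of the Lce1 and Sprr2 families are close paralogues, so these are not independent signals. In all 6 arrays together 0 of the 46 passed in limma and 2 had an unadjusted p below 0.05.

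The late cornified envelope gene Lce1a1 varied between arrays of each group. It stood at 12.36 and 8.88 in control, 11.24 and 7.59 in Ovol1 KO and 7.80 and 11.36 in DKO. Vim, which encodes the mesenchymal filament protein vimentin, had a mean of 10.59 ± 1.99 (SD, n = 2) in control, 11.35 ± 0.61 in Ovol1 KO and 12.79 ± 0.20 in DKO, and its log2 fold change of 2.20 in DKO against control did not pass in limma (SE 0.80, adjusted p = 0.27).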
